A study of Rattus norvegicus with 3 samples.

How the data were processed

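RNA was measured by sequencing in 3 populations from the enamel organs of Wistar Hannover rats: cells of the cervical loop, ameloblasts of the secretory stage and ameloblasts of the maturation stage. Per the labels, tissue came from 5 rats, libraries needed an RNA integrity number of at least 7, 1 cervical loop library was left out under that limit, and single-end reads of 75 bases were made. STAR 2.5.3a, Partek and the rat build rn6 are named in the submitters' processing notes. The annotation, the filter on genes, the normalisation and the model terms are not given in the sources used here.

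Each of the 3 samples is a single mean per gene and stage, so there is 1 sample per group. Per-library values were not analysed here, and no standard deviation could be computed. The authors deposited a comparison table with, for each gene and pair of stages, a p-value, a false discovery rate (FDR) and a ratio of the stage means. Per the file headers the stage means are least-squares means. Their unit is not stated in the headers, and they are called the authors' means here. Per the labels, 25000000 reads were made per library, but the reads counted per gene are not given in the sources used here, so no counting interval is given. The stage lists held the same values within 0.497%, and 11 symbols stood there as dates, so the comparison table was used. The deposited isoform tables, 1 per pair of stages, give a mean, a p-value and a ratio for each of 9949 transcripts and a p-value per gene for a change in isoform make-up.

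Several properties were checked on the values. The total column of the authors' deposited table equalled 3.99, 3.99 and 5.01 times the cervical loop, secretory and maturation means, added up. These multiples are near 4, 4 and 5, or 13 libraries. The labels give 14 if each of the 5 rats gave 3 libraries and 1 was left out, and this difference was not settled. The deposited p-values of the 3 pairs of stages fitted one another best at 6 error degrees of freedom, with a median mismatch of 0.340% against 2.77% at 7, the next best number. With rats as blocks, 13 libraries leave 6 error degrees of freedom and 14 leave 7. The interquartile range of the log ratio of standard errors implied by the p-values was 0.0531 if levels were tested on a log scale and 0.456 if not. By this check a ratio of stage means and its FDR measure different quantities. Where libraries vary widely, the direction taken from the means may not be that of the log difference. Acta1, for example, was 11-fold higher in maturation than in secretory cells with FDR = 0.972 in the authors' deposited table. In the secretory stage 3 genes had a mean below 0 and no ratio. A mean of 0.1 or less was treated as the floor, against which no fold is given: this held for 281 cervical loop, 377 secretory and 372 maturation means. The lowest maturation value, 0.0303, was shared by 62 genes.

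The deposited p-values were adjusted by the Benjamini-Hochberg method over all genes of a pair of stages, with a threshold of 0.05. The result equalled the authors' own FDR to within rounding of the numbers held, and for the isoform tables to within 0.00347. Direction is the sign of the difference of the stage means. A gene counted as high in a stage when it passed against both other stages in that direction. Beside that count were set the product of independent lists and 20 simulations of unchanged genes, which assumed 13 libraries blocked by rat. In a simulated set of the same number of genes, 200 genes raised in the secretory stage by 8 standard deviations were recovered at 99.5%, with 1 false call.

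In all 31 gene lists, 9 of them markers of cell types, were fixed before the data were examined, as were the tests, the alternatives not named below as later and the rule for named genes. The lists described here cover enamel matrix, maturation markers, pH and bicarbonate, calcium, clathrin, endocytic receptors, endosome trafficking, caveolae, lysosome, vacuolar ATPase, actin, microtubules, keratins and septins, junctions, cell cycle, progenitors, endoplasmic reticulum, iron, oxidative phosphorylation, apoptosis and the circadian clock. Results of 1 further list, which counts in the totals, are not reported here. Marker lists cover mesenchyme, odontoblast and bone, endothelium, myeloid, lymphoid, erythroid, muscle and pericyte, nerve and Schwann, and stratum intermedium cells. Each list was tested with cameraPR of limma 3.58.1 in R 4.3.3 on signed z values made from the deposited p-values, with an inter-gene correlation preset to 0.01. List p-values were adjusted by Benjamini-Hochberg over all lists and pairs of stages. An estimated correlation needs per-library values, so a preset correlation of 0.05 was the alternative. Random lists, drawn as if genes were independent, gave an adjusted p of 0.000845 at the smallest p they can reach. On z values simulated once as if genes were independent, 3 of 3 shifted lists among 31 were recovered, with 0 false calls. This does not show how many false calls arise where genes are correlated. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for the rest.

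Named genes were 22 fixed genes, and per pair of stages the 6 highest and 6 lowest folds among genes that passed, had a symbol and lay above the median of the higher stage. To these came up to 4 members of each described list with the smallest p, with further members that passed for each direction, and the 5 genes with the smallest isoform p, with any fixed gene that passed there. Muscle genes outside this rule were named after their values were seen. Of the gene names, 14068 (85.2%) were found in a RefSeq gene table of a later rat assembly, which was used for names only, so that no coordinates are given.

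The alternatives were an adjusted p under 0.01, Bonferroni adjustment, the authors' own FDR, leaving out the lowest 25% of genes by mean level, a fold of at least 2, centred log2 ratios, the log2 ratio as list statistic, 10000 random lists matched on level, pseudocounts of 1 and 0.1, upper-quartile scaling and scaling without the 10 most abundant genes. Lists without members shared with marker lists or with the muscle genes of the closing section were chosen after seeing the data. So were Fisher's exact test of lists among genes with changed isoforms, and list medians and means without members at the floor. Members at the floor are otherwise kept.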

Results

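Enamel is made by ameloblasts, epithelial cells that arise in the cervical loop, secrete enamel matrix and later remove it while mineral fills the space. RNA was compared between cells of the cervical loop, secretory-stage and maturation-stage ameloblasts from rat enamel organs, as 1 deposited mean per gene and stage. Per the labels, 25000000 reads were made per library. Endocytosis and the cytoskeleton, and how they change with stage, are the subject the series title names. Replicate error enters through the authors' p-values alone, and no spread can stand beside a mean. The number of libraries behind the means is inferred from the deposited totals as 4, 4 and 5.

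Enamel matrix genes took a large part of the secretory signal. Ameloblastin (Ambn), amelogenin (Amelx) and enamelin (Enam) together made up 18.2% of all summed means in secretory ameloblasts, against 0.659% in the cervical loop and 1.15% in maturation. The 10 genes with the largest mean took 32.5% of the secretory sum, 13.5% of the cervical loop sum and 14.3% of the maturation sum. These 10 include Ambn, Amelx and Enam, but also Col1a1, which is in the mesenchyme marker list. Rn7sl1 alone took 1.59% of the cervical loop, 2.77% of the secretory and 1.42% of the maturation sum. Col1a1, Col1a2 and Col3a1 together took 2.03%, 1.58% and 2.63% in the same order. The 75th percentile of the authors' means was 22.8, 22.7 and 22.6 in the 3 stages. Over all genes the median log2 ratio was -0.14 for secretory against cervical loop and -0.12 for maturation against cervical loop. Changes against the cervical loop are relative to these shifts. Of all genes, 41.8% passed for secretory against cervical loop, 42.9% for maturation against secretory and 57.8% for maturation against cervical loop. Counts of list members that passed are to be read beside these shares. Where the counts lie near them, they alone do not set a list apart from other genes.

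**Figure D1:**
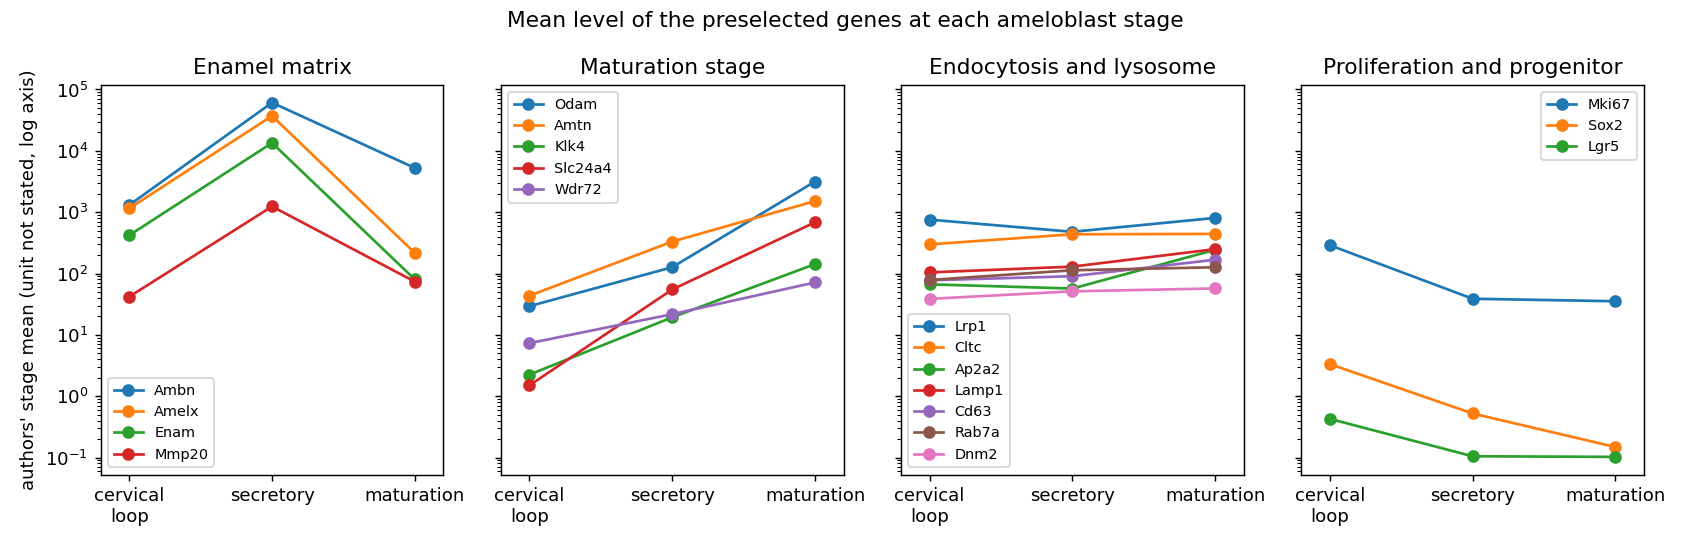
The authors' mean (unit not stated, log axis) of genes fixed beforehand, at the cervical loop, secretory and maturation stages; each line joins the 3 means of a gene, and no error bars are drawn because no per-library values were used. Ambn peaks in the secretory stage at 61048, and Odam is highest in maturation at 3159.

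The first comparison set secretory ameloblasts against cervical loop cells, as cells leave the proliferating epithelium. Matrix genes were far higher in secretory cells. Ambn stood at 1306 and 61048 in the authors' deposited table (46.7-fold higher, FDR = 0.00195). Amelx stood at 1152 and 37121 (32.2-fold higher, FDR = 0.00233) and Enam at 419.5 and 13468 (32.1-fold higher, FDR = 0.00314) in the authors' deposited table. Mmp20, the protease that processes matrix during secretion, was 29.6-fold higher in the authors' deposited table (FDR = 0.00341). Of 16 measured genes of the enamel matrix list, 13 rose, 0 fell and 3 did not pass (14 and 1 adjusted over the list alone, adjusted p = 1.59e-07). This list also holds genes that do not encode matrix proteins, such as Fam20c and Fam83h. Lamb3, which encodes a chain of an epithelial laminin, was 15.2-fold higher in the authors' deposited table.

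Among the highest folds by the naming rule were those of Fxyd4, a regulator of the sodium pump (93.2-fold, FDR = 0.000424), and Slc13a5, a citrate transporter (60.1-fold, FDR = 0.00163), in the authors' deposited table. Papln, Coro6 and Phactr3 followed at 59.4-fold, 55.5-fold and 32.4-fold higher in the authors' deposited table. The lowest were Ascl5 (140.2-fold lower, FDR = 0.000575) and Sall3 (126-fold lower, FDR = 0.00118), both of transcription factors, in the authors' deposited table. Ucma, the growth factor gene Fgf10 and Vwde were 102-fold, 89.8-fold and 76.6-fold lower in the authors' deposited table. Where a mean was low, the fold moved with the pseudocount. With 1 added to both means of the authors' deposited table, Fxyd4, Coro6 and Phactr3 were 22.6-fold, 17.7-fold and 10.2-fold higher, Ascl5 and Sall3 17.9-fold and 21.5-fold lower, and Ucma, Fgf10 and Vwde 11.6-fold, 16.6-fold and 27.4-fold lower.

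Cell division genes fell as a group. Of 47 members of the cell cycle list, 0 rose, 46 fell and 1 did not pass (the same counts adjusted over the list alone, adjusted p = 1.99e-17), with a median log2 ratio of -2.57. Mki67, a marker of dividing cells, stood at 289 and 38.8 in the authors' deposited table (7.46-fold lower, FDR = 0.000424), and the cyclin gene Ccnd1 was 10.3-fold lower. Sox2 and Lgr5, genes of epithelial stem cells, fell 6.38-fold and 4.07-fold in the authors' deposited table (FDR = 0.00933 and FDR = 0.0427). The progenitor list as a whole did not pass: of 28 members, 5 rose, 11 fell and 12 did not pass (the same counts adjusted over the list alone, adjusted p = 0.96, but the list passed downward with random lists, adjusted p = 0.0159). Sfrp5 was 49.1-fold lower and Igfbp5 3.08-fold higher in the authors' deposited table. With a pseudocount of 1 on the means of the authors' deposited table, Sox2, Lgr5 and Sfrp5 were 2.85-fold, 1.29-fold and 12.4-fold lower.

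Genes of the secretory pathway were higher. Of 64 genes of the endoplasmic reticulum and its stress response, 36 rose, 2 fell and 26 did not pass (38 and 2 adjusted over the list alone, adjusted p = 5.44e-10). Copa, of the coat of Golgi vesicles, was 1.48-fold and Dnajb9 3.51-fold higher, and Creld2 1.54-fold lower, in the authors' deposited table. Of 22 genes of the vacuolar ATPase, the proton pump of endosomes and lysosomes, 8 rose, 2 fell and 12 did not pass (11 and 2 adjusted over the list alone, adjusted p = 0.00153, or adjusted p = 0.119 with the log2 ratio as statistic). Atp6v1d and Atp6v0a1 were 2.77-fold and 3.08-fold higher in the authors' deposited table. Of 45 genes of oxidative phosphorylation, 13 rose, 2 fell and 30 did not pass (10 and 1 adjusted over the list alone, adjusted p = 0.00153, or adjusted p = 0.0556 with a preset correlation of 0.05, adjusted p = 0.0968 with the log2 ratio as statistic and adjusted p = 0.234 with random lists). Ndufa1 was 3.85-fold higher and Sdhb 1.24-fold lower in the authors' deposited table. Maturation markers were already higher: of 20 measured, 10 rose, 2 fell and 8 did not pass (the same counts adjusted over the list alone, adjusted p = 0.000336). Amtn and Wdr72 were 7.64-fold and 2.97-fold higher in the authors' deposited table (FDR = 0.0164 and FDR = 0.00395). Klk4 (2.25 and 19.3, FDR = 0.0891), Odam (29.3 and 127, FDR = 0.191) and Slc24a4 (1.5 and 54.9, FDR = 0.0941) did not pass in the authors' deposited table.

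Part of the endocytosis genes also rose. Of 51 clathrin genes, 20 rose, 7 fell and 24 did not pass (20 and 11 adjusted over the list alone, adjusted p = 0.0065, or adjusted p = 0.111 with a preset correlation of 0.05, adjusted p = 0.0514 with the log2 ratio as statistic and adjusted p = 0.106 with random lists). Clathrin heavy chain (Cltc) was 1.46-fold, the scission GTPase gene Dnm2 1.33-fold and the endocytic adaptor gene Numb 7.22-fold higher in the authors' deposited table. Hip1 and Ap2a2 were 1.64-fold and 1.17-fold lower in the authors' deposited table. Of 51 genes of endosome trafficking, 15 rose, 6 fell and 30 did not pass (the same counts adjusted over the list alone, adjusted p = 0.00717, or adjusted p = 0.115 with a preset correlation of 0.05, adjusted p = 0.105 with the log2 ratio as statistic and adjusted p = 0.122 with random lists). Rab7a, of late endosomes, was 1.44-fold higher and Rab11fip1 1.62-fold lower in the authors' deposited table. Of 45 lysosome genes, 14 rose, 1 fell and 30 did not pass (the same counts adjusted over the list alone, adjusted p = 0.00187, or adjusted p = 0.0603 with a preset correlation of 0.05, adjusted p = 0.11 with the log2 ratio as statistic and adjusted p = 0.167 with random lists). Man2b1, Ctsl and Lamp1 were 4.37-fold, 2.6-fold and 1.24-fold higher in the authors' deposited table, where Cd63 (77.5 and 90.4, FDR = 0.205) did not pass.

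The endocytic receptor list did not pass: of 26 genes, 4 rose, 7 fell and 15 did not pass (the same counts adjusted over the list alone, adjusted p = 0.65). Its median and mean log2 ratio, -0.02 and -0.03, had the opposite sign to its test. Lrp1, an endocytic receptor gene, was 1.58-fold lower, and Sort1 1.98-fold higher, in the authors' deposited table. Neither did the actin and microtubule lists pass. Of 80 actin genes, 16 rose, 16 fell and 48 did not pass (the same counts adjusted over the list alone, adjusted p = 0.304). Ezrin (Ezr), which ties actin to the membrane, was 2.66-fold higher, while Myh10, a non-muscle myosin, and Actb were 2.23-fold and 1.23-fold lower, in the authors' deposited table. Of 55 microtubule genes, 18 rose, 22 fell and 15 did not pass (19 and 23 adjusted over the list alone, adjusted p = 0.399). Mapre1 and Clip1 were 2.12-fold and 2.0-fold higher, and the tubulin gene Tuba1b 2.74-fold lower, in the authors' deposited table. Means of the actin and microtubule lists were negative (-0.08 and -0.11), where their medians and tests were positive. Of 34 junction genes, 10 rose, 5 fell and 19 did not pass (the same counts adjusted over the list alone, adjusted p = 0.0637), and the list did not pass. Cldn1, a tight junction gene, was 11.1-fold higher in the authors' deposited table.

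Markers of other cells moved in part. Of 14 endothelial markers, 3 rose, 0 fell and 11 did not pass (0 and 0 adjusted over the list alone, adjusted p = 0.0065, or adjusted p = 0.0803 with the log2 ratio as statistic), and of 9 markers of the stratum intermedium, the layer beside the ameloblasts, 3 rose, 0 fell and 6 did not pass (the same counts adjusted over the list alone, adjusted p = 0.0234, or adjusted p = 0.0713 with a preset correlation of 0.05, adjusted p = 0.0531 with the log2 ratio as statistic and adjusted p = 0.0996 with random lists). Flt1 was 1.64-fold and Alpl 2.11-fold higher in the authors' deposited table. Mesenchyme (adjusted p = 0.48), odontoblast and bone (adjusted p = 0.192) and myeloid markers (adjusted p = 0.987) did not pass. The mesenchyme list, with a median log2 ratio of -0.37, passed downward with random lists (adjusted p = 0.0158). Odontoblast and bone markers, with a median of -0.98, passed downward with the log2 ratio as statistic (adjusted p = 0.0181) and with random lists (adjusted p = 0.000845). In all, 6896 genes differed in the authors' deposited table, 2727 higher and 4169 lower in secretory cells. With a fold of at least 2 as well, 1099 were higher and 1763 lower.

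The second comparison, maturation against secretory ameloblasts, covers the change from laying down matrix to removing it. Matrix genes fell and maturation genes rose. Amelx stood at 37121 and 217 in the authors' deposited table (171-fold lower, FDR = 0.000897), and Enam was 168-fold lower (FDR = 0.00137). Ambn and Mmp20 were 11.6-fold and 16.8-fold lower in the authors' deposited table (FDR = 0.0185 and FDR = 0.0104). Of the 16 genes of the enamel matrix list, 2 rose, 13 fell and 1 did not pass (the same counts adjusted over the list alone, adjusted p = 0.00123). Tuft1 and Fam83h went the other way, 3.08-fold and 1.82-fold higher in the authors' deposited table. Of 20 maturation markers, 16 rose, 0 fell and 4 did not pass (the same counts adjusted over the list alone, adjusted p = 8.30e-05). Odam stood at 127 and 3159 (24.9-fold higher, FDR = 0.00661) and Slc24a4, a calcium exchanger, at 54.9 and 684 (12.5-fold higher, FDR = 0.00884) in the authors' deposited table. Klk4, the late protease, was 7.37-fold, Amtn 4.56-fold and Wdr72 3.29-fold higher in the authors' deposited table (FDR = 0.014, FDR = 0.0223 and FDR = 0.00215).

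Among the highest folds by the naming rule were Sowahb (103-fold), the amino acid transporter gene Slc6a14 (84.5-fold), Tnni1 (76.1-fold) and Cck (63-fold) in the authors' deposited table. Hpd, at the floor in secretory cells, stood at 8.09 in maturation in the authors' deposited table (FDR = 0.00015). Tnni1 encodes a troponin of skeletal muscle (FDR = 0.000999 in the authors' deposited table). Beside it, the muscle genes Myh4 (1.96 and 52.8, FDR = 0.491) and Mb (0.621 and 20.3, FDR = 0.833), named after their values were seen, did not pass in the authors' deposited table. Ctnna2 (474-fold), the signalling genes Shh (271-fold) and Wnt3a (247-fold) and Gba3 (228-fold) were lower in the authors' deposited table. With a pseudocount of 1 on the means of the authors' deposited table, Sowahb, Slc6a14, Tnni1 and Cck were 10.8-fold, 30.1-fold, 17.6-fold and 28.4-fold higher, and Ctnna2, Shh, Wnt3a and Gba3 168-fold, 35-fold, 32.9-fold and 26.4-fold lower. Oc90 and Dspp, a dentin matrix gene, stood at 48.9 and 22.2 in secretory cells and at the floor in maturation in the authors' deposited table (FDR = 0.00182 and FDR = 0.0467).

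The secretory pathway turned the other way: of 64 endoplasmic reticulum genes, 8 rose, 40 fell and 16 did not pass (9 and 42 adjusted over the list alone, adjusted p = 6.93e-06). Kdelr3, Sec31a and Copa were 4.22-fold, 1.85-fold and 1.71-fold lower, and Dnajc3 1.76-fold higher, in the authors' deposited table. Of 45 oxidative phosphorylation genes, 26 rose, 2 fell and 17 did not pass (29 and 2 adjusted over the list alone, adjusted p = 6.99e-06, or adjusted p = 0.344 with the log2 ratio as statistic). Sdhb and Atp5f1a were 1.6-fold and 1.33-fold higher, and Ndufa1 2.45-fold lower, in the authors' deposited table. The cell cycle list did not pass: of 47 genes, 3 rose, 5 fell and 39 did not pass (3 and 4 adjusted over the list alone, adjusted p = 0.497). Mki67 stood at 38.8 and 35.3 in the authors' deposited table (FDR = 0.586). The progenitor list did not pass either: of 28 genes, 4 rose, 12 fell and 12 did not pass (4 and 13 adjusted over the list alone, adjusted p = 0.0532, but the list passed downward with the log2 ratio as statistic, adjusted p = 6.15e-06 and with random lists, adjusted p = 0.0164). Among its members with the smallest p, Ptch1, Gli1 and Hhip were 14-fold, 39.9-fold and 76.5-fold lower in the authors' deposited table (13.3-fold for Hhip with a pseudocount of 1).

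Lysosome and proton pump genes rose. Of 45 lysosome genes, 20 rose, 3 fell and 22 did not pass (22 and 3 adjusted over the list alone, adjusted p = 0.000472). Lamp1 was 1.93-fold (FDR = 0.000181), Cd63 1.86-fold and Ctsf 4.04-fold higher, and Man2b1 3.19-fold lower, in the authors' deposited table. Of 22 vacuolar ATPase genes, 13 rose, 2 fell and 7 did not pass (the same counts adjusted over the list alone, adjusted p = 0.00413, or adjusted p = 0.0633 with the log2 ratio as statistic). Atp6v1e1 was 3.33-fold higher and Atp6v0a4 2.59-fold lower in the authors' deposited table. Beside these and the other lists that rose from secretory to maturation, of 16 myeloid markers, 12 rose, 0 fell and 4 did not pass (the same counts adjusted over the list alone, adjusted p = 0.000244). Cd74, Lyz2 and the leukocyte gene Ptprc were 3.99-fold, 4.59-fold and 2.73-fold higher in the authors' deposited table. Of 14 endothelial markers, 6 rose, 0 fell and 8 did not pass (the same counts adjusted over the list alone, adjusted p = 0.0126, or adjusted p = 0.0603 with a preset correlation of 0.05 and adjusted p = 0.122 with the log2 ratio as statistic), and of 19 mesenchyme markers, 7 rose, 1 fell and 11 did not pass (the same counts adjusted over the list alone, adjusted p = 0.00996, or adjusted p = 0.0657 with a preset correlation of 0.05 and adjusted p = 0.143 with the log2 ratio as statistic). Without members shared with marker lists, a setting chosen after seeing the data, the lysosome list gave adjusted p = 0.000982. This setting keeps 43 of the 45 genes, so it cannot tell lysosome genes of ameloblasts from those of other cells.

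Of 26 endocytic receptor genes, 12 rose, 6 fell and 8 did not pass (the same counts adjusted over the list alone, adjusted p = 0.0341, or adjusted p = 0.144 with a preset correlation of 0.05). Tfrc, the transferrin receptor gene, stood at 188 and 3249 in the authors' deposited table (17.3-fold higher, FDR = 0.000321), Lrp1 was 1.69-fold higher and Sort1 3.21-fold lower. Of 51 endosome trafficking genes, 18 rose, 4 fell and 29 did not pass (the same counts adjusted over the list alone, adjusted p = 0.020, or adjusted p = 0.163 with a preset correlation of 0.05 and adjusted p = 0.56 with the log2 ratio as statistic). Rab7a was 1.12-fold higher, and Rab27a, of secretory granules, 5.16-fold lower, in the authors' deposited table. The clathrin list did not pass: of 51 genes, 21 rose, 9 fell and 21 did not pass (21 and 10 adjusted over the list alone, adjusted p = 0.0915, but the list passed upward with random lists, adjusted p = 0.0158). Ap2a2, of the plasma membrane adaptor, stood at 56.9 and 244 in the authors' deposited table (4.28-fold higher, FDR = 6.11e-05), Synj1 was 4.45-fold higher and Numb 4.11-fold lower. Cltc (436 and 442, FDR = 0.859) and Dnm2 (51.2 and 57.1, FDR = 0.248) did not pass in the authors' deposited table.

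The actin list did not pass: of 80 genes, 28 rose, 13 fell and 39 did not pass (30 and 14 adjusted over the list alone, adjusted p = 0.12, but the list passed upward with random lists, adjusted p = 0.0445). Myh14, a non-muscle myosin, and Arpc2, of the complex that branches actin, were 6.62-fold and 1.98-fold higher, and Arpc5l 1.47-fold lower, in the authors' deposited table. Ezr (171 and 176, FDR = 0.792) and Actb (1362 and 1157, FDR = 0.080) did not pass in the authors' deposited table. The microtubule list did not pass: of 55 genes, 23 rose, 16 fell and 16 did not pass (the same counts adjusted over the list alone, adjusted p = 0.401). Tubb3 was 12.2-fold lower and the motor gene Kif1b 1.85-fold higher in the authors' deposited table. Of 34 junction genes, 21 rose, 5 fell and 8 did not pass (21 and 6 adjusted over the list alone, adjusted p = 0.00573, or adjusted p = 0.0713 with a preset correlation of 0.05 and adjusted p = 0.122 with the log2 ratio as statistic). Cldn4 and F11r were 27.5-fold and 2.85-fold higher, and Cldn8 6.5-fold lower, in the authors' deposited table (17.6-fold and 1.82-fold for Cldn4 and Cldn8 with a pseudocount of 1). Of 9 stratum intermedium markers, 6 rose, 1 fell and 2 did not pass (7 and 1 adjusted over the list alone, adjusted p = 0.0367, or adjusted p = 0.0982 with a preset correlation of 0.05). In all, 7089 genes differed in the authors' deposited table, 3598 higher and 3491 lower in maturation. With a fold of at least 2 as well, 1544 were higher and 1269 lower.

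**Figure D2:**
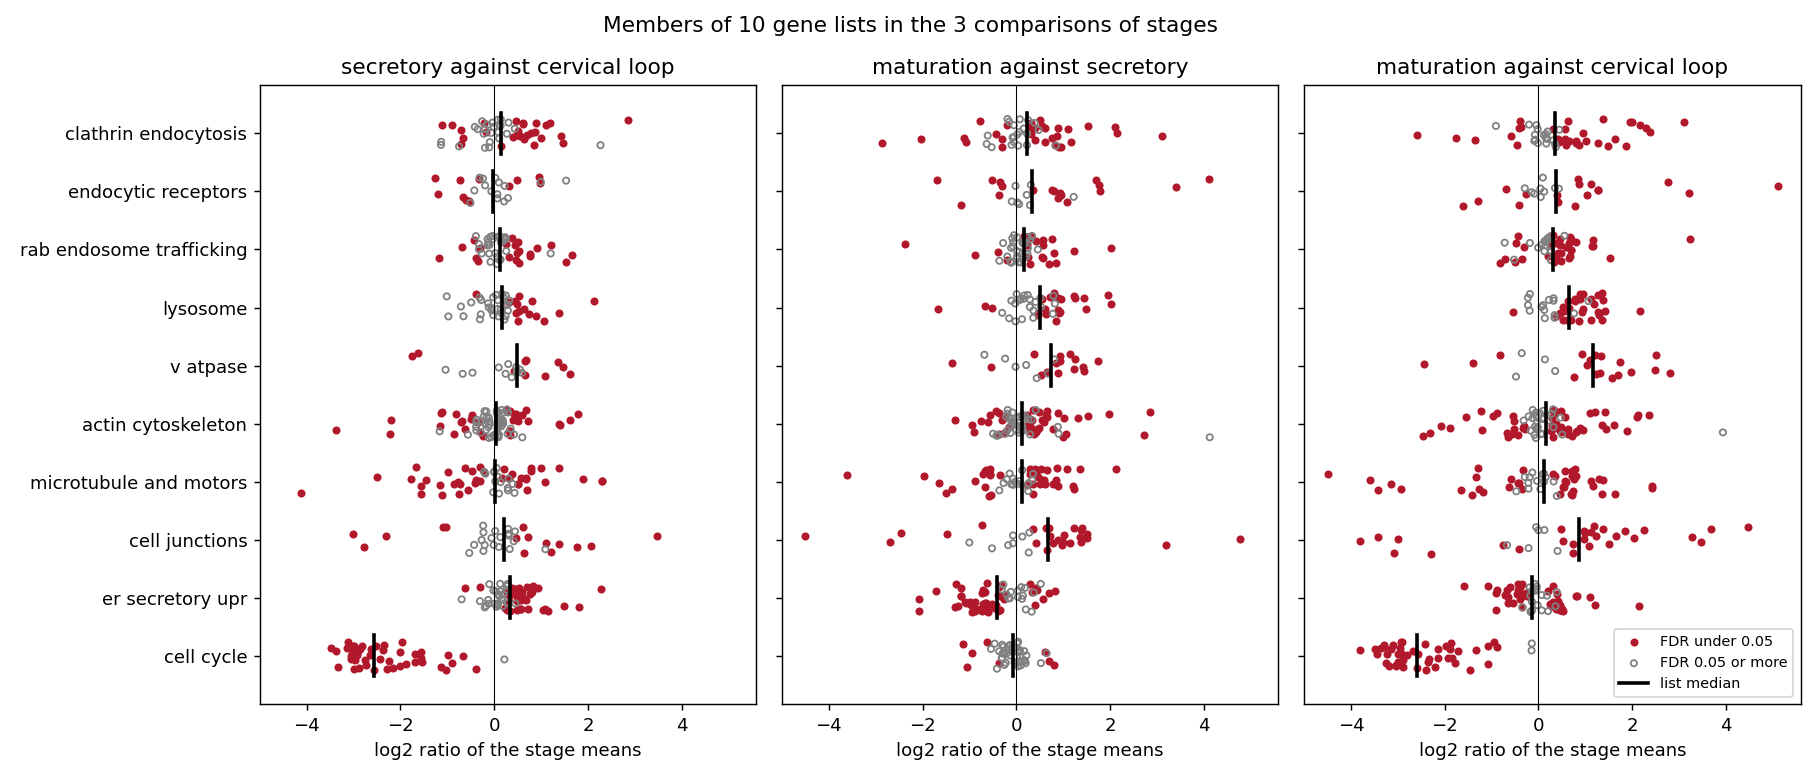
Log2 ratio of the stage means (x axis) for each member of 10 gene lists (y axis) in the 3 comparisons of stages; filled points had an FDR under 0.05, open points did not, black bars mark list medians, and the vertical scatter within a list is random. Cell cycle genes have a median of -2.57 for secretory and -2.58 for maturation against the cervical loop, and the vacuolar ATPase list has 1.16 for maturation against the cervical loop.

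Maturation against cervical loop, the last comparison, spans the whole course. Of 20 maturation markers, 19 rose, 0 fell and 1 did not pass (the same counts adjusted over the list alone, adjusted p = 1.23e-08). Slc24a4 was 455-fold (FDR = 0.00125), Odam 108-fold (FDR = 0.00141), Klk4 63.3-fold, Amtn 34.9-fold and Wdr72 9.78-fold higher in the authors' deposited table. Slc34a2, a phosphate transporter, and Gpr155 were 476-fold and 137-fold higher in the authors' deposited table. Slc6a14 and the casein gene Csn3, at the floor in the cervical loop, stood at 45.1 and 34.3 in maturation in the authors' deposited table. Shh stood at 152 and 0.144 in the authors' deposited table (1056-fold lower, FDR = 0.000178). Vwde, Dspp, Cyp26c1, Mpped1 and Ascl5 stood at 41, 81.7, 39.5, 31.1 and 19.4 in the cervical loop and at the floor in maturation in the authors' deposited table. Of 47 cell cycle genes, 0 rose, 45 fell and 2 did not pass (the same counts adjusted over the list alone, adjusted p = 9.78e-15). Mki67, Cenpf and Sox2 were 8.19-fold, 13.9-fold and 22.5-fold lower in the authors' deposited table, and Lgr5 4.17-fold. With a pseudocount of 1 on the means of the authors' deposited table, Slc24a4 and Slc34a2 were 274-fold and 164-fold higher, and Shh, Sox2 and Lgr5 134-fold, 3.77-fold and 1.29-fold lower.

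Of the 16 genes of the enamel matrix list, 7 rose, 2 fell and 7 did not pass (the same counts adjusted over the list alone, adjusted p = 0.0352, or adjusted p = 0.123 with a preset correlation of 0.05 and adjusted p = 0.0529 without the lowest 25% of genes). The mean log2 ratio of this list was -0.22, where its median was 0.64. The 1 member at the floor was Dspp, a dentin matrix gene that is also in the odontoblast and bone list. Without it, a setting chosen after seeing the data, the mean was 0.44 and the median 0.81. With the log2 ratio as the statistic the list went down without passing (adjusted p = 0.869). Ambn and Tuft1 were 4.02-fold and 5.31-fold higher, and Sp6 4.34-fold lower, in the authors' deposited table. Amelx (1152 and 217, FDR = 0.177), Enam (419.5 and 80.0, FDR = 0.291) and Mmp20 (41.9 and 73.7, FDR = 0.104) did not pass in the authors' deposited table. The endoplasmic reticulum list did not pass: of 64 genes, 19 rose, 26 fell and 19 did not pass (19 and 27 adjusted over the list alone, adjusted p = 0.905). Kdelr3 was 3.01-fold lower and Dnajb9 4.41-fold higher in the authors' deposited table. Of 45 oxidative phosphorylation genes, 34 rose, 0 fell and 11 did not pass (35 and 0 adjusted over the list alone, adjusted p = 1.63e-10). Ndufs1 was 1.56-fold higher in the authors' deposited table. The progenitor list did not pass: of 28 genes, 7 rose, 14 fell and 7 did not pass (9 and 14 adjusted over the list alone, adjusted p = 0.304, but the list passed downward with the log2 ratio as statistic, adjusted p = 8.87e-07 and with random lists, adjusted p = 0.0158). Hhip was 174-fold lower (29.2-fold with a pseudocount of 1), and Tp63, of basal epithelial cells, 2.52-fold higher, in the authors' deposited table.

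Endocytosis and lysosome genes were higher in maturation than in the cervical loop. Of 51 clathrin genes, 24 rose, 8 fell and 19 did not pass (the same counts adjusted over the list alone, adjusted p = 0.000172). Ap2a2 (3.66-fold, FDR = 4.52e-05), Hip1r (4.46-fold), Cltc (1.48-fold) and Dnm2 (1.48-fold) were higher in the authors' deposited table. Of 51 endosome trafficking genes, 28 rose, 7 fell and 16 did not pass (31 and 7 adjusted over the list alone, adjusted p = 4.51e-05, or adjusted p = 0.0761 with the log2 ratio as statistic). Rab7a was 1.61-fold higher and Rab11fip1 1.76-fold lower in the authors' deposited table. Rab5a, fixed beforehand, is not among the genes listed. Of 45 lysosome genes, 29 rose, 1 fell and 15 did not pass (the same counts adjusted over the list alone, adjusted p = 6.96e-08). Lamp1 (2.4-fold, FDR = 5.47e-05), Cd63 (2.17-fold) and Ctsf (4.5-fold) were higher in the authors' deposited table. Of 22 vacuolar ATPase genes, 15 rose, 3 fell and 4 did not pass (the same counts adjusted over the list alone, adjusted p = 0.000105). Atp6v1a stood at 78 and 547 in the authors' deposited table (7.01-fold higher). Of 26 endocytic receptor genes, 12 rose, 5 fell and 9 did not pass (the same counts adjusted over the list alone, adjusted p = 0.0231, or adjusted p = 0.126 with a preset correlation of 0.05 and adjusted p = 0.0558 with random lists). Tfrc was 34.5-fold higher in the authors' deposited table, where Lrp1 (756 and 807, FDR = 0.365) did not pass. Beside these and the other lists that rose for maturation against cervical loop, of 16 myeloid markers, 10 rose, 0 fell and 6 did not pass (the same counts adjusted over the list alone, adjusted p = 0.000411), and of 14 endothelial markers, 11 rose, 0 fell and 3 did not pass (the same counts adjusted over the list alone, adjusted p = 0.000207). Cd14 was 4.08-fold and Kdr 2.41-fold higher in the authors' deposited table.

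Of 80 actin genes, 33 rose, 19 fell and 28 did not pass (34 and 19 adjusted over the list alone, adjusted p = 0.0191, or adjusted p = 0.203 with a preset correlation of 0.05, adjusted p = 0.171 with the log2 ratio as statistic and adjusted p = 0.148 with random lists). Ezr was 2.73-fold higher, and Myh10 and Actb were 2.9-fold and 1.44-fold lower, in the authors' deposited table. The microtubule list did not pass: of 55 genes, 24 rose, 17 fell and 14 did not pass (25 and 18 adjusted over the list alone, adjusted p = 0.128), with a median log2 ratio of 0.12 and a mean of -0.11. Klc2 was 2.17-fold higher and Stmn1 10.8-fold lower in the authors' deposited table. Of 34 junction genes, 21 rose, 7 fell and 6 did not pass (the same counts adjusted over the list alone, adjusted p = 0.00123). Cldn1, Nectin3 and F11r were 22.1-fold, 11-fold and 9.66-fold higher in the authors' deposited table. Of 9 stratum intermedium markers, 7 rose, 1 fell and 1 did not pass (the same counts adjusted over the list alone, adjusted p = 0.00573). Mesenchyme (adjusted p = 0.0775) and odontoblast and bone markers (adjusted p = 0.401) did not pass. Odontoblast and bone markers, with a median log2 ratio of -1.70 (-1.31 without the 2 members at the floor), passed downward with the log2 ratio as statistic (adjusted p = 2.75e-05) and with random lists (adjusted p = 0.000845). In all, 9554 genes differed in the authors' deposited table, 3987 higher and 5567 lower in maturation. With a fold of at least 2 as well, 1753 were higher and 2558 lower.

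Ion transport genes were followed through the 3 comparisons. For secretory against cervical loop, of 30 genes of pH and bicarbonate, 11 rose, 3 fell and 16 did not pass (the same counts adjusted over the list alone, adjusted p = 0.00334, or adjusted p = 0.0556 with a preset correlation of 0.05). For maturation against secretory the list did not pass: 11 rose, 5 fell and 14 did not pass (the same counts adjusted over the list alone, adjusted p = 0.304, but the list passed upward with the log2 ratio as statistic, adjusted p = 0.048). For maturation against cervical loop, 19 rose, 2 fell and 9 did not pass (19 and 3 adjusted over the list alone, adjusted p = 0.000411). Slc4a4, a bicarbonate transporter, stood at 14.5, 86.5 and 162, and Cftr, a chloride channel, at 5.11, 19.9 and 116, in the cervical loop, secretory and maturation stages of the authors' deposited table. Of 32 calcium genes, 13 rose, 4 fell and 15 did not pass (13 and 5 adjusted over the list alone, adjusted p = 0.0133, or adjusted p = 0.111 with a preset correlation of 0.05) for secretory against cervical loop. For maturation against secretory they did not pass as a list: 15 rose, 6 fell and 11 did not pass (17 and 6 adjusted over the list alone, adjusted p = 0.0917, but the list passed upward with random lists, adjusted p = 0.00321). Against the cervical loop in maturation, 15 rose, 6 fell and 11 did not pass (the same counts adjusted over the list alone, adjusted p = 0.00626, or adjusted p = 0.0713 with a preset correlation of 0.05). Stim1, a sensor of calcium stores, stood at 25, 88.1 and 232, Atp2a2, which fills them, at 144, 565 and 915, and Itpr1, a release channel, at 109, 1909 and 67.9 in the 3 stages of the authors' deposited table.

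By the overall test of stage in the authors' deposited table, which is separate from the tests of pairs, 11099 genes (67.2%) differed. The cervical loop had 3074 genes higher than in both other stages, secretory ameloblasts 1320 and maturation ameloblasts 2410. Independent lists of these sizes would share 1405, 576 and 869 genes, and simulated unchanged genes gave a mean of 0.05, 0 and 0. The pair of comparisons behind each count shares a stage, so the lists are not independent. In the simulations no gene changed at all, so counts near 0 were set by the adjustment and do not test the observed counts.

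Few of the genes tested passed for a change in isoform make-up, which does not show that the others kept theirs. For secretory against cervical loop 48 of 4050 genes passed in the authors' deposited tables, for maturation against secretory 73 of 4051 and for maturation against cervical loop 113 of 4050. Of these, 34, 47 and 82 also differed as whole genes. For maturation against secretory the smallest p was that of Macf1, which links actin and microtubules (FDR = 9.50e-08 in the authors' deposited table). The share of transcript Macf1-202 in the gene's summed mean went from 18.8% to 39.6% in the authors' deposited table, and Macf1-201 and Macf1-204 had equal means. Plod2-201, of a lysyl hydroxylase, went from 80.9% to 34.8% (FDR = 7.83e-07), Mtus1-203 from 29.4% to 49.7% (FDR = 1.65e-07), Bsg-201 from 0.517% to 7.7% (FDR = 4.90e-05) and Sytl4-202 from 20.1% to 1.97% (FDR = 0.000334) in the authors' deposited tables. Amelx passed too (FDR = 0.00302), with Amelx-203 from 70.0% to 54.8% and Amelx-205 from 17.2% to 41.6% in the authors' deposited tables.

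**Figure D3:**
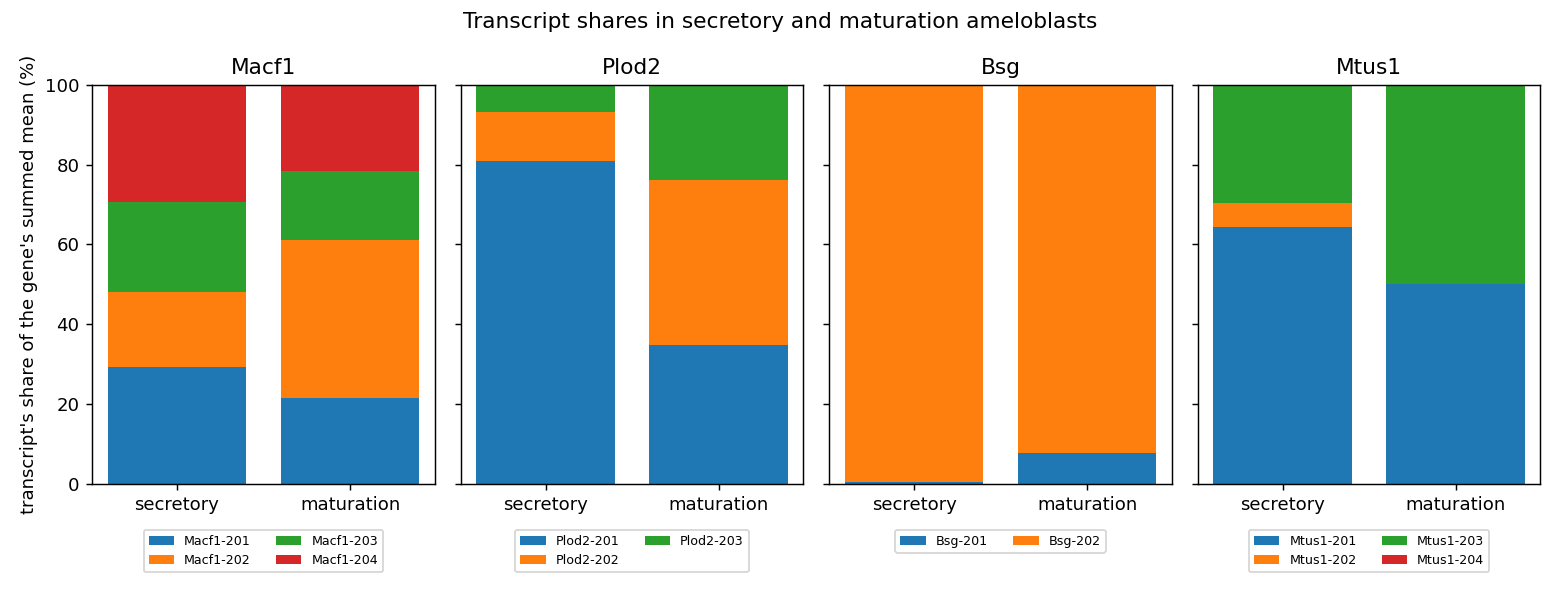
Share of each transcript in its gene's summed mean (percent, stacked bars from 0) in secretory and maturation ameloblasts for 4 genes whose isoform make-up changed; no error bars are drawn because no per-library values were used. Macf1-202 went from 18.8% to 39.6% and Plod2-201 from 80.9% to 34.8%.

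For maturation against cervical loop the smallest p was that of Tln2, a talin that couples integrins to actin (FDR = 1.45e-12 in the authors' deposited table). Tln2-201 went from 3.22% to 55.3%, and Tln2-202 and Tln2-205, which had equal means, each went from 45.6% to 21.6% in the authors' deposited table. LOC100912489, Vcan, Slc25a16 and Nme4 followed (FDR = 4.34e-07, FDR = 5.64e-05, FDR = 5.64e-05 and FDR = 6.09e-05 in the authors' deposited table). For secretory against cervical loop the smallest p were those of Slc25a16, Abcb1b, Vcan, Dclk1 and Spag5 in the authors' deposited table. Slc25a16-202 went from 35% to 73.7%, Abcb1b-203 from 68.3% to 11.1% and Spag5-202 from 3.6% to 37.9% there. None of the 22 fixed lists other than cell type markers was enriched among the genes with changed isoforms of any comparison, and marker lists were not tested there. The lowest adjusted p of Fisher's exact test, two-sided and chosen after seeing the data, was 0.426.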

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

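Of the settings in this section, leaving out lists' members shared with marker lists, or at the floor, was chosen after seeing the data. No library could be left out, no libraries split another way and no correlation between genes estimated, because each stage is a single deposited mean. The labels give 25000000 reads per library but no counts per gene, so what depth limits was not tested. Gene counts were identical with the authors' own FDR, and gene, stage-high and isoform counts stayed within 1.5 times without the lowest 25% of genes by level. Bonferroni adjustment gave 112, 206 and 427 genes for secretory against cervical loop, maturation against secretory and maturation against cervical loop, and 316 by the separate overall test of stage. A fold of at least 2 gave 2862, 2813 and 4311. An adjusted p under 0.01 gave 4047 and 4164 for the first and second comparison, with the other counts within 1.5 times. Stage-high genes numbered 1747 in the cervical loop, 782 in secretory and 1385 in maturation at 0.01 (3914 in all), and 1259, 476 and 974 with a fold of at least 2 (2709 in all). Genes with changed isoforms numbered 14, 34 and 42 at 0.01, and 9, 19 and 22 with Bonferroni. These settings are stricter by construction. Of 93 list tests 46 passed, against 25 with a correlation of 0.05, which is also stricter by construction. The log2 ratio as statistic gave 37, with 17 calls lost and 8 gained in the direction of the test, and random lists 52, with 8 lost and 13 gained. The filter on level gave 45, with 1 lost, and lists without shared members 46. The enamel matrix list for maturation against cervical loop went down, not up, with the log2 ratio as statistic (adjusted p = 0.869). The muscle and pericyte list for maturation against secretory, down by its test without passing, passed upward with the log2 ratio as statistic (adjusted p = 1.17e-07) and with random lists (adjusted p = 0.000845). In that comparison 2 of its 15 members passed higher (Rgs5 and Cspg4) and 3 lower. Acta2, Tagln and Cnn1 were those lower, with log2 ratios of -1.32, -1.10 and -3.64. Myh4 and Mb, with log2 ratios of 4.75 and 5.03, did not pass. Large ratios that do not pass weigh in the log2 ratio but little in the main test. The cause of the changes was not tested. Centring could turn only called genes of small log2 ratio, because the calls come from p-values that were not recomputed, so it does not test the split of higher and lower genes. Ratios of summed means stayed within 1.5 times under both scalings. Of 975 named folds a pseudocount of 1 moved 139 by over 1.5 times and 0.1 moved 36. Without its member at the floor, Dspp, the mean log2 ratio of the enamel matrix list for maturation against cervical loop turned from -0.22 to 0.44. Means of 2 lists that did not pass turned likewise. That of keratins and septins for maturation against cervical loop went from 0.18 to -0.18. That of microtubules for maturation against secretory went from 0.0017 to -0.021.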

Other observations

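Tests of abundant transcripts, of myeloid markers and of muscle genes were chosen after the results were seen, and that of a scaling offset before. Of 25 iron genes, 10 rose, 2 fell and 13 did not pass (the same counts adjusted over the list alone, adjusted p = 0.0338, or adjusted p = 0.143 with a preset correlation of 0.05) from secretory to maturation ameloblasts. Against the cervical loop, 13 rose, 4 fell and 8 did not pass in maturation (the same counts adjusted over the list alone, adjusted p = 0.00481, or adjusted p = 0.0556 with a preset correlation of 0.05), and the list did not pass for secretory cells (adjusted p = 0.131), where its median was -0.0037 and its mean 0.22. Beside them, 12 of 16 myeloid markers rose from secretory to maturation ameloblasts (adjusted p = 0.000244) and 10 of 16 against the cervical loop in maturation (adjusted p = 0.000411). The ferritin genes Fth1 and Ftl1 stood at 243, 342 and 2955 and at 53.6, 51.9 and 675 in the 3 stages of the authors' deposited table. Of 11 caveolae genes, 4 rose, 0 fell and 7 did not pass for secretory against cervical loop (the same counts adjusted over the list alone, adjusted p = 0.0216, or adjusted p = 0.0713 with a preset correlation of 0.05, adjusted p = 0.061 with the log2 ratio as statistic and adjusted p = 0.185 with random lists). Maturation gave adjusted p = 0.987 against secretory and adjusted p = 0.144 against cervical loop, and whether the comparisons differ was not tested. Cav1 and Cav2 stood at 42.3, 118 and 36.6 and at 11.1, 87.3 and 12.6 in the 3 stages of the authors' deposited table.

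Keratin and septin genes did not pass as a list (adjusted p = 0.768 for secretory against cervical loop, adjusted p = 0.304 for maturation against secretory, adjusted p = 0.891 for maturation against cervical loop). For maturation against secretory the list passed upward with the log2 ratio as statistic (adjusted p = 0.0112). Krt14 stood at 295, 542 and 1691 and Krt75 at 5.94, 0.557 and 0.648 in the authors' deposited table. In the same order, apoptosis genes (adjusted p = 0.791, adjusted p = 0.0917, adjusted p = 0.0637) and clock genes (adjusted p = 0.0768, adjusted p = 0.613, adjusted p = 0.144) did not pass. For maturation against cervical loop the apoptosis list passed upward with random lists (adjusted p = 0.0497). Bhlhe40, a clock repressor gene, was 4.2-fold higher in maturation than in secretory cells in the authors' deposited table (FDR = 0.000562). Lymphoid (adjusted p = 0.0687, adjusted p = 0.85, adjusted p = 0.0637), erythroid (adjusted p = 0.523, adjusted p = 0.141, adjusted p = 0.0683), nerve and Schwann (adjusted p = 0.612, adjusted p = 0.768, adjusted p = 0.773) and muscle and pericyte markers (adjusted p = 0.954, adjusted p = 0.896, adjusted p = 0.987) did not pass. For secretory against cervical loop, lymphoid markers passed upward with random lists (adjusted p = 0.014). Muscle and pericyte markers passed upward with the log2 ratio as statistic (adjusted p = 1.17e-07) and with random lists (adjusted p = 0.000845) for maturation against secretory, and upward with the log2 ratio as statistic (adjusted p = 2.37e-09) and with random lists (adjusted p = 0.000845) for maturation against cervical loop. Of the 15 muscle and pericyte markers, 2 rose and 3 fell for maturation against secretory. For maturation against cervical loop, 1 rose and 4 fell. Signs differed within some lists that did not pass. The muscle and pericyte list went down by its test for secretory against cervical loop, with a mean of 0.46 and a median of -0.30, and for maturation against secretory, with a median of 2.81. Without its 4 members at the floor, the mean and median for secretory against cervical loop were 0.19 and -0.56. The caveolae list went down by its test for maturation against secretory, with a mean of -0.05 (-0.31 without the 1 member at the floor) and a median of 0.11. Tests went up for apoptosis in secretory against cervical loop cells (median -0.10, mean -0.13), for lymphoid markers in maturation against secretory cells (median -0.03) and, in maturation against cervical loop cells, for keratins (median -0.03) and nerve markers (mean -0.19). Odontoblast and bone markers gave adjusted p = 0.891 for maturation against secretory, where they passed downward with the log2 ratio as statistic (adjusted p = 0.00779). Their mean log2 ratio there was -0.97, or -0.22 without the 2 members at the floor.

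A list of 36 muscle genes is called sarcomere genes here, though some, such as Ckm, Mb, Ryr1 and Casq2, are not of the sarcomere itself. Over these 36 the median log2 ratio of maturation against the cervical loop was 3.13, or 2.23 over the 28 above the floor in both stages. Yet 4 of the 36 (11.1%) passed, Tnni1 and Ryr1 higher and Tnnc1 and Casq2 lower. Genes with a log2 ratio over 2, a maturation mean of at least 0.456 and a cervical loop mean above the floor were then compared. Of these, 2 of 10 sarcomere genes outside the fixed muscle markers passed, against 97.2% of 561 others (two-sided Fisher's exact p = 1.18e-10, genes not being independent replicates). The others had no upper limit on level, so level was not matched. A rise of like size in every maturation library is therefore not settled by this. Skeletal muscle in a minority of the maturation libraries, which would raise the mean and its error together, was not tested apart from the genes that prompted it. Abundant muscle transcripts stood at 52.8 (Myh4, FDR = 0.277), 34.7 (Neb, FDR = 0.17), 23.8 (Acta1, FDR = 0.542) and 20.3 (Mb, FDR = 0.356) in maturation in the authors' deposited table. Without per-library values muscle in a minority of libraries stays open. So do a rise in every library, alike or widely varied, and a change of Tnni1 in the ameloblasts.

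Myeloid markers were higher in maturation than in secretory dissections. Their median lay 0.63 log2 units above the mesenchyme median (two-sided permutation p over genes = 0.00927, genes not being independent replicates). A larger share of all other cell types need not raise every marker alike, because the rise depends on each marker's level beforehand. The difference therefore cannot argue against such a share. Mesenchyme, endothelial and stratum intermedium markers also passed upward there. Odontoblast and bone, lymphoid, erythroid, muscle and nerve markers did not pass. The rise was not confined to genes shared with the lysosome list, as 10 of the 14 myeloid markers outside that list passed upward. With 12 of 16 markers passing in all and so few shared, a high count there was fixed beforehand. It is therefore no test of a cause. More leukocytes around maturation ameloblasts, a larger share of other cell types in general, or expression by the ameloblasts themselves may underlie the rise. These cannot be told apart here. Lyz2 and Cd74 stood at 299.9 and 217 in maturation in the authors' deposited table.

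More genes were lower than higher against the cervical loop. Maturation, where the abundant secretory transcripts are scarce, also had a median log2 ratio of -0.12 (95% bootstrap interval over genes -0.14 to -0.11). Such transcripts therefore do not account for the shift in maturation. The interval resamples genes, not libraries, and leaves out any error in the scaling of a stage. Whether these transcripts made the shift in secretory cells, a median of -0.14, cannot be told from maturation. A scaling offset would shift all levels alike, but the median of the top quartile of mean level lay above that of the bottom by 0.40 for secretory (0.36 to 0.43) and 0.29 for maturation (0.25 to 0.35). The bound set for this difference was 0.3, which the maturation interval spans, so an offset cannot be told apart from a change that goes with level. A true difference between stages may also account for it and was not tested.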
